A study of Mus musculus with 4 samples.

How the data were processed

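RNA from P19 cells was measured on Affymetrix gene-level arrays, with biotin-labelled targets made from total RNA. There were 4 arrays, 1 each for wild-type and Ctcfl-line cells, undifferentiated or after 4 days in 10 µM retinoic acid. Per the labels the Ctcfl line had been without doxycycline for 2 days. The labels differ on wild-type cells: the growth description gives ordinary culture, whereas the sample characteristics give 2 µg/ml doxycycline. The deposited values are log2 signals that the authors made by RMA in Affymetrix Expression Console, which corrects background, normalizes between arrays and summarises each probe set. The submitters' processing notes also name Transcriptome Analysis Console. Versions and the genome build were not stated in the sources used here. No further normalization was applied.

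The table held 41345 probe sets, of which 23521 had exactly 1 gene symbol, 1814 had several and 16010 were not in the probe annotation. A gene was represented by its single-symbol probe set with the highest mean, which gave 22180 genes; 1082 of them had more than 1 probe set. Genes whose highest signal on the 4 arrays was below log2 6 were left out, and 18310 remained. Array medians over all probe sets lay between 6.95 and 6.96, and correlations between arrays between 0.961 and 0.985. As a guide to background, olfactory receptor genes had medians between 4.68 and 4.78 on the arrays, and 242 of 1105 (21.9%) were past the filter. The only error that single arrays give is technical: log2 differences of probe sets of the same gene varied with an SD between 0.233 and 0.354, from 791 genes. Chromosomes came from a gene table on assembly GRCm38.p6.

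The comparisons were retinoic acid in each line, the Ctcfl line against wild type in each state, and the difference of the retinoic acid differences between the lines. Log2 differences and genes at least 2-fold apart were counted without a test. Effects averaged over line or state came from limma (lmFit and eBayes) with retinoic acid and line as additive terms, which leaves 1 residual degree of freedom per gene, a prior of 5.49 degrees of freedom, and the interaction as error. P-values were two-sided and adjusted by Benjamini-Hochberg over all genes past the filter, with a threshold of 0.05. The same p-values were also adjusted over each list alone, with no correction across lists or effects. Fold changes were computed from log2 values.

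The 31 gene lists cover differentiation, lineages, the germ line, genome organisation, metabolism and stress. For each list of at least 3 genes past the filter, the median log2 difference was ranked among 10000 random lists of the same size, matched on mean expression in 20 bins. A list stood apart at a percentile of at most 0.5 or at least 99.5. Random genes are independent and list members are often regulated together, so this describes these arrays and is no test of conditions. Of 155 medians (31 lists in 5 comparisons), 40 stood apart, where independent genes would give 1.55.

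Named genes followed a rule. Ctcfl and Ctcf were always eligible, as were the 10 genes with the highest and the 10 with the lowest difference in each comparison. Up to 4 genes with the largest differences were added from each list that stood apart or was the subject of a comparison, and the 10 smallest p in each direction from the limma fits. Predicted genes, clone names and small RNAs were counted but not named by the rule, and any name from outside it is said to be chosen after its value was seen. Groups, comparisons, the 31 lists, filters, the naming rule and all alternatives but 1 were fixed before the data were examined. A further list, of Nodal and Smad targets, was written after these results were known and before its own test.

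The procedure was tested on simulated data, made from 18310 genes with 200 changed genes for each effect. Their noise had a spread close to limma's prior for these data, and no gene responded differently in the 2 lines. In the data the difference of responses was at least 2-fold in 486 genes, though single arrays cannot tell these from noise. The rates thus hold under the model's own assumptions only. For retinoic acid, limma recovered 65.0% of 2-fold and 99.0% of 4-fold changes, and 9.4% of its 181 calls were unchanged genes. For the line it recovered 57.0% and 100.0%, and 7.6% of its 170 calls were unchanged genes. Of 40 random lists of 30 genes 0 stood apart, and 40 of 40 lists shifted by log2 0.3 did. This was run on the line difference in retinoic acid alone. Most list medians that stood apart there were smaller than 0.3, so recovery of such sizes was not shown. Lists of genes regulated together were not tried.

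The alternatives were no filter, a filter at log2 7, quantile normalization of the 4 arrays, the mean of a gene's probe sets, a 3-fold threshold, a variance prior that follows mean expression, a 2-fold limit on the limma calls and list means in place of medians. An alternative chosen after seeing the data set the remaining split of the arrays against each other, which is the difference of responses with the line effect as error. Probe sets with several symbols or none in the annotation were left out of the comparisons because their gene was not settled. The software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.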

Results

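Gene expression was measured in P19 cells, a mouse embryonal carcinoma line that differentiates when it is exposed to retinoic acid. Wild-type cells were compared with a clone of the line that carried an inducible Ctcfl transgene, called the Ctcfl line here. Ctcfl, also known as BORIS, is a zinc finger protein of the testis and a paralog of the insulator protein Ctcf. Each line was measured undifferentiated and after 4 days in 10 µM retinoic acid, which gives 4 conditions with 1 array each. The Ctcfl line had been without doxycycline for 2 days, which switches the transgene on in its Tet-Off system. The design asks how gene expression differs with Ctcfl in undifferentiated and in differentiating cells. Of 22180 genes with a value, 18310 had a log2 signal of at least 6 on 1 or more arrays and were compared. There were no replicates, so the number of arrays limits the precision of every value, and differences within a line or a state are given without a test. A fold or log2 difference that rests on a signal below log2 6, the filter's limit, is not exact. This holds for values of Cftr, Dcn, Hoxa5, Nxf3, Pcdhb3, Pcdhb15 and Rex2, and for the difference of responses of Nepn.

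Ctcfl itself had a log2 signal of 7.86 in undifferentiated wild-type cells and 10.41 in undifferentiated cells of the Ctcfl line. In retinoic acid the signals were 7.13 and 9.56. Ctcfl was thus 5.85-fold higher in the Ctcfl line without retinoic acid and 5.36-fold higher with it. Whether its probe set reads the transgene, the chromosomal gene or both was not settled, so these folds are of the signal and not of either transcript alone. In a limma fit with retinoic acid and line as additive terms, Ctcfl rose 5.60-fold with the line (log2 2.49 ± 0.15, SE, adjusted p = 0.00645). It was higher in 2 of 2 states, as the folds above already show. The paralog Ctcf had a line effect of log2 0.15 (adjusted p = 0.784 in limma).

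The first pair of comparisons asks what retinoic acid did in each line. Tshz1 and Hox genes were among the largest increases in both. Tshz1, a zinc finger transcription factor, was higher by log2 5.20 in wild-type cells and 4.91 in the Ctcfl line. The homeobox gene Hoxa5 was higher by log2 5.02 and 4.60 in the same order. Averaged over the lines, Tshz1 rose 33.3-fold (log2 5.06 ± 0.16, SE, adjusted p = 7.92e-05 in limma). Hoxa5 and its cofactor Meis1 each rose 28.0-fold (adjusted p = 0.00012 for both), and Hoxb1 rose 14.5-fold (adjusted p = 0.000335). Of the 36 Hox genes measured, 20 rose, 0 fell and 16 did not pass in limma; adjusted over the list alone, 23 rose and 0 fell. The Hox median was log2 0.95 in wild-type cells and 1.43 in the Ctcfl line.

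Of 33 genes of the retinoic acid response, 18 rose with retinoic acid, 2 fell and 13 did not pass in limma; adjusted over the list alone, 19 rose and 2 fell. Rarb, a retinoic acid receptor, rose 10.1-fold (log2 3.34 ± 0.15, SE, adjusted p = 0.000402 in limma), and Dhrs3, which reduces retinaldehyde to retinol, rose by log2 3.46 (adjusted p = 0.000506). Cyp26a1, the enzyme that oxidises retinoic acid, rose 7.76-fold (adjusted p = 0.00719), with differences of log2 2.15 in wild-type cells and 3.77 in the Ctcfl line. Crabp2, a cellular retinoic acid binding protein, rose 7.41-fold (adjusted p = 0.0046). The list median was log2 1.43 in wild-type cells and 0.81 in the Ctcfl line.

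Pluripotency genes were lower with retinoic acid. Tdgf1, the Nodal coreceptor, fell 17.5-fold (log2 -4.13 ± 0.23, SE, adjusted p = 0.000571 in limma). Otx2, a homeobox gene of the epiblast and forebrain, fell 10.7-fold (adjusted p = 0.00278), and Utf1, a chromatin protein of pluripotent cells, fell 10.6-fold (adjusted p = 0.000529). The de novo DNA methyltransferase Dnmt3b fell 7.04-fold (adjusted p = 0.000529). Pou5f1 and Nanog, core pluripotency factors chosen here after their values were seen, fell 2.99-fold (adjusted p = 0.00743) and 3.92-fold (adjusted p = 0.00513). Sox2, chosen in the same way and shared with neural progenitors, differed by log2 -0.46 in wild-type cells and -0.18 in the Ctcfl line and did not pass. Of 46 pluripotency genes, 2 rose, 19 fell and 25 did not pass; adjusted over the list alone, 8 rose and 25 fell. The list median was log2 -0.50 in wild-type cells and -0.54 in the Ctcfl line.

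Markers of the embryonic lineages moved in more than 1 direction. Among 42 neural progenitor genes, 8 rose, 3 fell and 31 did not pass; adjusted over the list alone, 12 rose and 4 fell. Pax6, a regulator of the neural tube, rose 3.15-fold (adjusted p = 0.0188 in limma), and Sox1, an early neural plate marker, rose 3.41-fold (adjusted p = 0.0111). Zic2, a zinc finger gene of the dorsal neural tube, fell 3.62-fold (adjusted p = 0.00184). Of 53 neuron genes, 3 rose, 5 fell and 45 did not pass; adjusted over the list alone, 4 rose and 8 fell. Dcx, a microtubule protein of young neurons, rose 2.67-fold, whereas the neurofilament gene Nefl fell 4.03-fold (adjusted p = 0.00985 and 0.0266). In the endoderm list of 28 genes, 4 rose and 1 fell; adjusted over the list alone, 6 rose and 1 fell. Gata6, a regulator of primitive endoderm, rose 8.47-fold (adjusted p = 0.000608), and Foxa1, a forkhead factor of endoderm, rose 7.92-fold (adjusted p = 0.00199). In the primitive streak and mesoderm list of 26 genes, 5 rose and 1 fell, with the same counts adjusted over the list alone. Meox1, a homeobox gene of the somites, rose 4.98-fold (adjusted p = 0.00265). Of 35 genes of mesenchyme and smooth muscle, 6 rose and 1 fell; adjusted over the list alone, 13 rose and 2 fell. The matrix proteoglycan Dcn rose 14.0-fold (adjusted p = 0.00401), from signals of log2 5.94 and 5.90 that are not clearly above background. Trophoblast and epithelium genes had medians of log2 -0.04 in wild-type cells and -0.44 in the Ctcfl line; of 18, 2 rose and 2 fell, and adjusted over the list alone 2 rose and 5 fell.

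Of 19 clustered protocadherins, neuronal adhesion genes whose promoters bind Ctcf, 8 rose with retinoic acid, 0 fell and 11 did not pass, and adjusted over the list alone 11 rose and 0 fell. Pcdhb3 rose 2.89-fold (adjusted p = 0.00377 in limma). Pcdhb21 also rose (adjusted p = 0.00249), but its signal of log2 4.53 in undifferentiated wild-type cells was below the olfactory receptor median of 4.78 on that array, so no fold is given. The list median was log2 0.44 in wild-type cells and 1.08 in the Ctcfl line. Of 26 genes of glycolysis and hypoxia, 1 rose and 5 fell; adjusted over the list alone, 2 rose and 10 fell. Pfkp and Pfkl, which encode phosphofructokinase, fell by 1.57 and 1.22 on the log2 scale (adjusted p = 0.0152 and 0.00738). The median of that list was log2 -0.41 in wild-type cells and -0.40 in the Ctcfl line. Ribosomal protein genes had a median of log2 -0.11 in wild-type cells and -0.22 in the Ctcfl line, and proteasome genes -0.08 and -0.27; 1 of 62 ribosomal protein genes fell and 0 of 38 proteasome genes changed in limma, and 0 of either list passed when adjusted over the list alone.

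Across all 18310 genes, 473 were at least 2-fold higher and 479 at least 2-fold lower with retinoic acid in wild-type cells, and 588 and 274 in the Ctcfl line. The lines shared 276 of the higher genes, where 15.2 would be shared by independent draws, and 164 of the lower genes, where 7.17 would be; 0 genes were 2-fold apart in opposite directions. Pearson's r between the lines was 0.678 and Spearman's rho 0.538 across genes, which are not independent replicates. The additive limma fit called 1217 genes, of which 770 rose and 447 fell. It leaves 1 residual degree of freedom per gene and takes the difference between the lines as error, so a gene with unequal responses passes less easily.

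**Figure D1:**
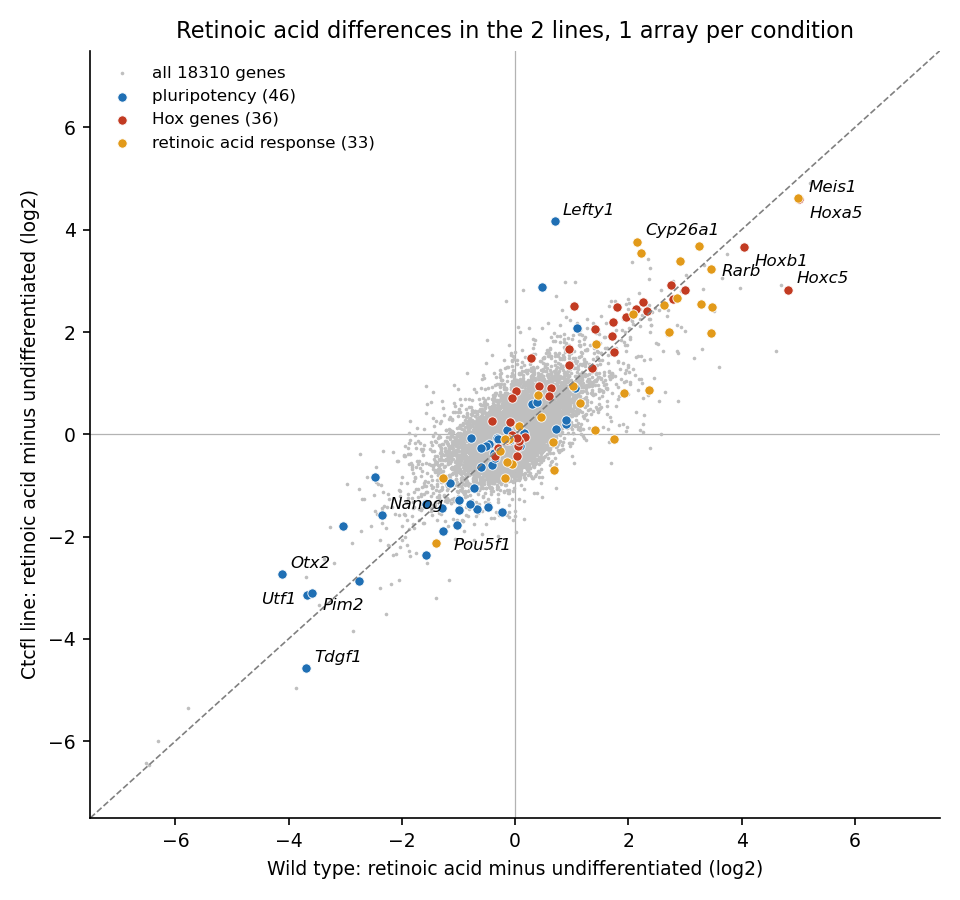
Log2 difference between retinoic acid and undifferentiated cells in wild-type cells (x axis) and in the Ctcfl line (y axis), with 1 point per gene for 18310 genes, members of 3 gene lists in colour and equal differences on the dashed line. Hoxa5 and Meis1 lie at the upper right and Tdgf1 and Otx2 at the lower left.

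The next comparison asks what distinguished the Ctcfl line in both states. The line differs from wild type in its integrated vectors and clonal origin as well as in Ctcfl, and the labels conflict on whether wild-type cells also had doxycycline, so each effect is of all that differed together. In the limma fit, 5 genes rose with the line and 3 fell. Besides Ctcfl, Grb10, an imprinted gene for an adaptor of insulin signalling, rose 6.56-fold (log2 2.71 ± 0.16, SE, adjusted p = 0.00645). The adhesion receptor gene Adgrg1 rose 4.78-fold (adjusted p = 0.0199), the GABA receptor subunit Gabra5 rose 4.71-fold (adjusted p = 0.0149) and Tex16, a testis-expressed gene, rose 3.97-fold (adjusted p = 0.0236). Tspan6, a tetraspanin gene, fell 22.7-fold (log2 -4.51 ± 0.20, SE, adjusted p = 0.00439). The chloride channel gene Cftr fell 17.6-fold (adjusted p = 0.00645), to signals of log2 5.88 and 5.74 that are not clearly above background, and Jmjd8 fell 4.44-fold (adjusted p = 0.0199). Each of the 8 genes had its direction in 2 of 2 states. A call in this fit all but requires that, since its error is the difference between the states. Nodal, a signal of the early embryo, was 2.52-fold higher in undifferentiated cells and 3.07-fold higher in retinoic acid and did not pass (adjusted p = 0.0667).

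Few testis and germ line genes differed between the lines. Of 50 genes of the germ line and meiosis, 0 rose and 0 fell with the line in limma, over all genes and adjusted over the list alone, and 0 were at least 2-fold apart in either state. Their median was log2 -0.04 in undifferentiated cells and -0.07 in retinoic acid. Of 17 testis antigen genes 1, Tex16, rose, and 1 rose adjusted over the list alone; their medians were log2 -0.04 and -0.22, and Nxf3, an RNA export factor gene, was 4.32-fold lower in retinoic acid. Of 47 imprinted genes 1, Grb10, rose, and adjusted over the list alone 2 rose and 1 fell. Genes of CTCF and cohesin had medians of log2 0.17 and -0.01, and 0 of 19 changed with the line, also adjusted over the list alone. Clustered protocadherins were the list that lay above its random lists in both states, with medians of log2 0.22 and 0.52. In limma 0 of these 19 genes changed with the line, but adjusted over the list alone 5 rose and 0 fell. Of the pluripotency genes 0 changed with the line, but adjusted over the list alone 8 rose and 1 fell. Counts adjusted over a list alone were not corrected across lists.

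In limma the line effect passed an unadjusted p of 0.05 in 1796 genes and the adjusted threshold in 8. Quantile normalization of the arrays raised the 8 to 23 and a variance prior that follows mean expression raised them to 15, with all 8 among them.

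In undifferentiated cells alone, 133 genes were at least 2-fold higher and 200 at least 2-fold lower in the Ctcfl line. The highest among named genes was Rtl8c, a gene derived from a retrotransposon, at 8.54-fold. The histone gene H2bc9 was 3.91-fold higher. Rassf4, of the Ras association family, was 5.51-fold lower, Txnip, an inhibitor of thioredoxin, was 4.63-fold lower, and the growth factor receptor gene Fgfr2 was 3.34-fold lower. Genes of the integrated stress and amino acid response were lower as a group, with a median of log2 -0.56 and 33 of 34 below 0. Slc7a11, the cystine transporter, was 2.94-fold lower, and Chac1, which degrades glutathione, was 2.70-fold lower. Primitive streak and mesoderm genes had a median of log2 0.14, with Wnt3, a signal of the primitive streak, 3.36-fold higher and the T-box gene Eomes 2.67-fold higher. With a 3-fold threshold 49 genes were apart in place of 333, 31 of them higher and 18 lower, so that the higher genes were then in the majority.

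In retinoic acid, 152 genes were at least 2-fold higher and 73 at least 2-fold lower in the Ctcfl line. Several genes of pluripotent cells were among the highest. The Nodal antagonists Lefty1 and Lefty2 were 6.48-fold and 4.42-fold higher, Dppa2, a chromatin factor of pluripotent cells, was 5.76-fold higher, and the nuclear receptor gene Nr0b1 was 3.83-fold higher. Nanog was 2.99-fold higher, again chosen after its value was seen. Of the 46 pluripotency genes, 8 were at least 2-fold higher and 0 at least 2-fold lower, while the list median was log2 0.07.

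Furthest below wild type in the Ctcfl line after retinoic acid were Tspan6 and Cftr, with log2 differences of -4.87 and -3.70. Nepn, a proteoglycan gene of the gut endoderm, was 11.4-fold lower. Hapln1, a link protein of the matrix, was 6.06-fold lower and Flrt2, an adhesion protein, was 5.39-fold lower. Osr1, a regulator of intermediate mesoderm, was 4.28-fold lower. Endoderm genes had a median of log2 -0.26 in this comparison, with Ttr, a thyroid hormone carrier, 2.32-fold lower and Gata6 2.23-fold lower. The retinoic acid response list had a median of log2 -0.14, with Tfap2a, Ret and Aldh1a2 2.64-fold, 2.61-fold and 2.47-fold lower, whereas Cyp26a1 was 3.42-fold higher. Hox genes had a median of log2 0.25: Hoxc8, Hoxa9 and Hoxc9 were 2.43-fold, 2.08-fold and 2.04-fold higher and Hoxc5 2.06-fold lower. Imprinted genes had a median of log2 -0.11, with 4 of 47 at least 2-fold lower and 2 at least 2-fold higher; the list no longer stood apart with the mean of probe sets. The growth factor gene Igf2 was 3.43-fold lower and Zim1 2.76-fold lower, whereas Grb10 was 7.28-fold higher and the zinc finger gene Plagl1 2.27-fold higher. Among the protocadherins, Pcdhb15 was 2.25-fold and Pcdhb18 2.07-fold higher.

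Further lists stood apart from random lists in this comparison. Stress and amino acid genes had a median of log2 0.27, and genes of unfolded protein and heat shock 0.15, with the chaperone gene Hspb1 higher by log2 1.14. Cholesterol synthesis genes had a median of log2 -0.17, with Insig1, a sterol sensor, 2.34-fold lower. The medians were log2 -0.13 for glycolysis and hypoxia, -0.13 for ribosomal proteins and -0.23 for replication-dependent histones. Some of these no longer stood apart under another setting: glycolysis and histones without the filter on low signals, glycolysis also with quantile normalization and with the mean of probe sets, and histones and unfolded protein genes with list means in place of medians.

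Between the states, the line differences of the 18310 genes had a Pearson's r of 0.258 and a Spearman's rho of 0.212. The states shared 26 genes at least 2-fold higher, where independent draws would share 1.10, and 12 genes at least 2-fold lower, where they would share 0.797.

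**Figure D2:**
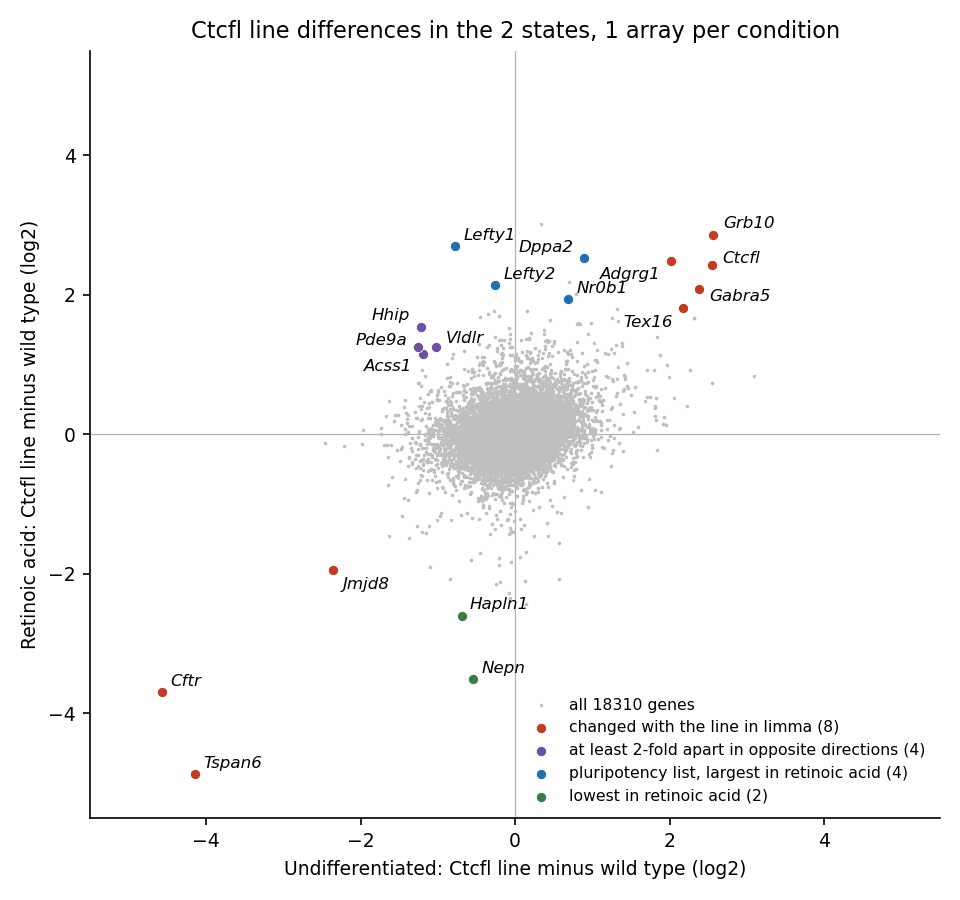
Log2 difference between the Ctcfl line and wild type in undifferentiated cells (x axis) and in retinoic acid (y axis), with 1 point per gene for 18310 genes and named genes in colour. Grb10, Ctcfl, Tspan6 and Cftr lie far from 0 on both axes, while Lefty1 and Nepn are far from 0 in retinoic acid.

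The last comparison asks how far the response to retinoic acid differed between the lines, as the difference of the retinoic acid differences. It was at least 2-fold in 486 genes, higher in the Ctcfl line in 348 and lower in 138. Its SD over all genes was log2 0.411. Probe sets of the same gene varied with SDs of 0.324 and 0.354 in the retinoic acid differences of wild-type and Ctcfl-line cells. How many of the 486 exceed technical noise was therefore not settled. Lefty1 had the largest positive value among named genes, log2 3.47, with signals of 9.47 without and 10.17 with retinoic acid in wild-type cells and of 8.70 and 12.87 in the Ctcfl line. Hhip, a Hedgehog binding protein, followed at log2 2.77. Twist1, a mesodermal transcription factor, had log2 -2.65. Nepn had log2 -2.97, which rests on a signal of 5.61 in undifferentiated cells of the Ctcfl line and is not exact.

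Stress and amino acid response genes made up the list with the highest median in this comparison, log2 0.83, with 32 of 34 members above 0. In wild-type cells the list had a median of log2 -1.13 with retinoic acid and in the Ctcfl line -0.26. Ddit3, a transcription factor of the stress response, differed by log2 2.14 between the lines, Slc7a11 by 1.83 and Chac1 by 1.82. In limma 3 of the 34 fell with retinoic acid and 0 rose; adjusted over the list alone 18 fell and 1 rose. Cth, an enzyme of cysteine synthesis, fell 3.95-fold (adjusted p = 0.00145) and the arginine transporter gene Slc7a3 fell 4.49-fold (adjusted p = 0.00362). With the line, 0 of the 34 changed, also adjusted over the list alone. That term averages the states, where the line differences had medians of log2 -0.56 (undifferentiated) and 0.27 (retinoic acid). Their gap counts as error, so the 0 does not show that the lines were alike.

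**Figure D3:**
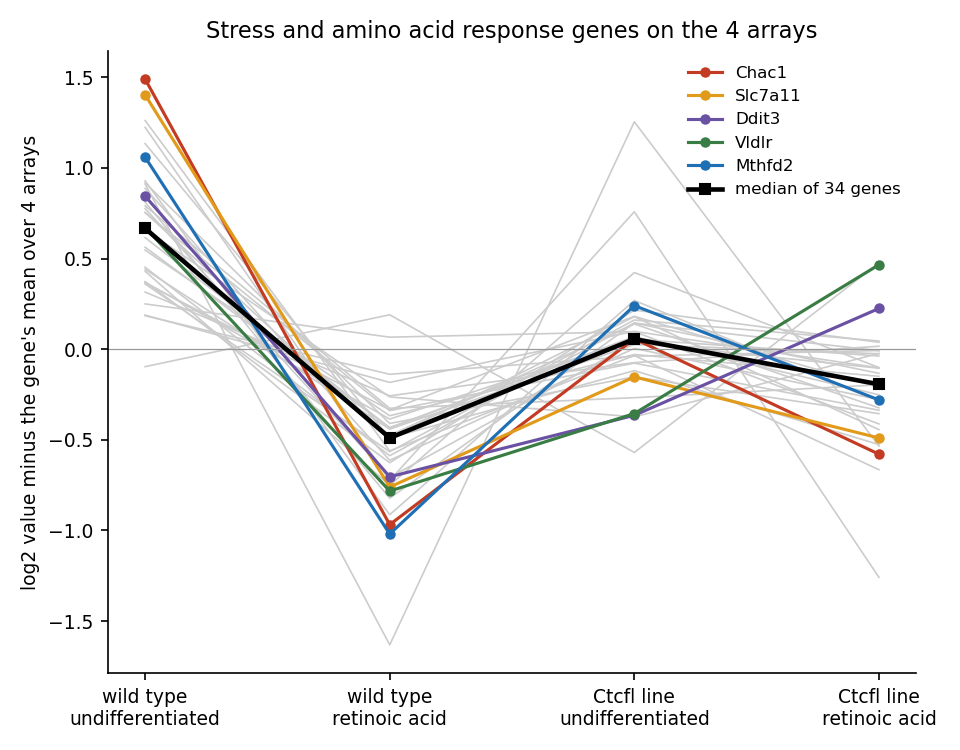
Signals of the 34 integrated stress and amino acid response genes on each of the 4 arrays, as log2 deviations from each gene's mean. Of the 34 genes, 32 were highest in undifferentiated wild-type cells and 28 were lowest in wild-type cells with retinoic acid.

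Primitive streak and mesoderm genes had a median difference of log2 -0.37 in the response, with Foxf1, a forkhead factor of lateral mesoderm, at log2 -1.83 and the endothelial receptor gene Kdr at log2 -1.54. Trophoblast and epithelium genes had a median of log2 -0.39, cholesterol synthesis genes -0.37, retinoic acid response genes -0.23 and endoderm genes -0.22. Rdh10, which makes retinaldehyde, had log2 -1.84. Glia genes had a median of log2 0.27 and clustered protocadherins 0.20. With 1 array per condition the difference of responses has no error of its own. A limma fit of it, chosen after seeing the data, called 0 genes. At an unadjusted p under 0.05 it had 336 of 18310, below the share of 0.05 that unchanged genes alone would give. The error of this fit holds the line effect, so the 0 does not show that responses were alike. Nor do the 336 show that responses differed. The protocadherin value lay within the range of random lists with a filter at log2 7 and with quantile normalization.

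**Figure D4:**
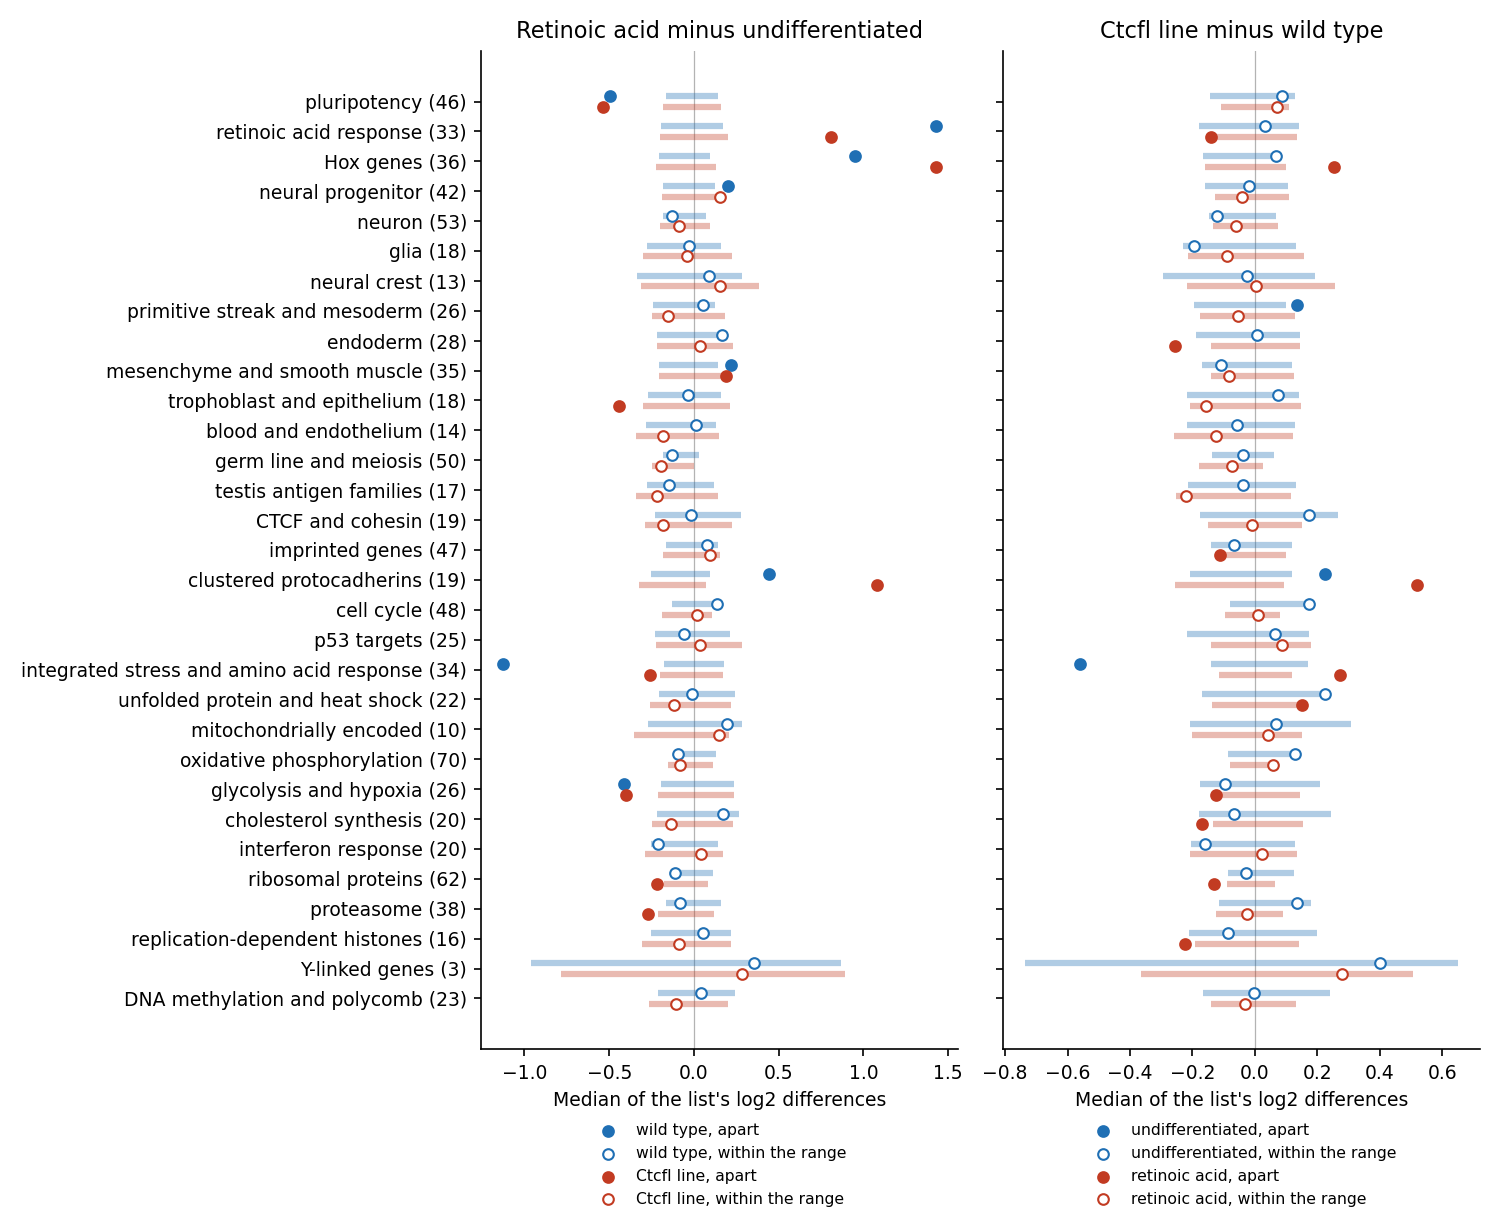
Median log2 difference of each of 31 gene lists, with the number of genes in parentheses, for retinoic acid minus undifferentiated cells by line (left) and for the Ctcfl line minus wild type by state (right). Bars give the range of 10000 random lists beyond which a list stood apart, and filled points lie outside it, as the stress and amino acid list does in all 4 comparisons.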

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

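The tests of doxycycline, of a single culture, of chromosome segments and of the neighbour of Tex16, of the clone and vectors, and of remaining undifferentiated cells were chosen only after the result was seen.

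In 4 genes the Ctcfl line lay at least 2-fold below wild type in undifferentiated cells and at least 2-fold above it in retinoic acid, where independent draws would give 1.66; 0 genes went the other way, and the difference between the states was not tested against replicates, with 1 array per condition. Acss1, an acetyl-CoA synthetase gene, differed by log2 -1.19 and then 1.15. Hhip differed by log2 -1.22 and then 1.55. Pde9a, a phosphodiesterase gene, differed by log2 -1.26 and then 1.25. Vldlr, a lipoprotein receptor gene that is also on the stress list, differed by log2 -1.03 and then 1.25. Probe sets without a listed gene were not used in the comparisons; of 10332 past the filter, 276 were at least 2-fold higher with retinoic acid in both lines, where independent draws would share 52.3, and 22 were at least 2-fold lower in both, where they would share 1.09.

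The stress and amino acid list was also below wild type in undifferentiated cells, with a median of log2 -0.56, and above it in retinoic acid, with a median of log2 0.27, and this difference was not tested against replicates either. Doxycycline in the wild-type medium, acting alike in both states, would put both medians below 0; the median in retinoic acid was 0.2721, but 1 culture per condition gives no spread between cultures to hold it against, so doxycycline stays open. Array-wide scaling would move matched random lists as far, and the list's difference of responses lay at percentile 100 of them. The state of a single culture stays open too: 32 of the 34 genes were highest on the undifferentiated wild-type array, and with 1 culture per condition medium or density may account for that level. An unequal effect of retinoic acid in the lines, the biological explanation the design gives, cannot be told apart from either.

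The 8 genes called with the line may reflect the clone. For the 6 called genes other than Ctcfl and Tex16, gain or loss of a chromosome segment that reaches neighbouring genes would move the 3 nearest expressed genes on each side. Yet their 36 neighbours had a median of log2 -0.0196 in the direction of the called gene (spread between genes 0.1177). Taken by called gene, the neighbour medians lay between -0.21 and 0.07. The highest single value was 0.60, Gabrg3 beside Gabra5, and Cttnbp2 beside Cftr had a line effect of log2 -0.58, in the direction of Cftr. A change confined to 1 gene, or one that reaches a single neighbour, as may be at Gabra5 and Cftr, stays open. Beside Tex16 the next gene, 4933403O08Rik, had a line effect of log2 1.99, as Tex16 did, while the other 5 neighbours lay between -0.24 and 0.13; a gain of a segment that holds Tex16 and its neighbour cannot be told apart from shared regulation of the pair. Clone, vectors or doxycycline rather than Ctcfl cannot be told apart from Ctcfl itself, since 0 arrays hold the Ctcfl line kept with doxycycline.

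Of the pluripotency genes, 8 were at least 2-fold higher in the Ctcfl line after retinoic acid, here including Tbx3 and Rex2, chosen after their values were seen. Remaining undifferentiated cells would make a mix of wild type with retinoic acid and the undifferentiated Ctcfl line, which cannot exceed both. Lefty1, Lefty2 and Tbx3 lay at least 2-fold above both, which argues against such a mix for these 3. Their excess over wild type was set by how the 8 were picked. That over the undifferentiated line was not set by it, but is not free of it. Both use the same array of the Ctcfl line with retinoic acid, whose error would raise both. Each value is from 1 array, and wild type stood in for differentiated Ctcfl-line cells. Remaining cells that had themselves changed in retinoic acid were not measured and stay open. Nodal lay above both by log2 0.58 and is left open. For the genes between both, Nanog, Nr0b1, Dppa2 and Rex2 would need shares of undifferentiated cells from 23.2% to 91.1%. The highest, of Rex2, rests on a wild-type signal of log2 5.88 with retinoic acid and is not exact. Over all 19 pluripotency genes with a share, these included, the median was 4.75% (bootstrap SD 3.81), with 4 below 0. So 1 share does not account for all 19 alike, but these genes were picked as higher, which favours shares above the median. The bootstrap gives no spread between cultures, so remaining undifferentiated cells stay open there. A higher Nodal signal, the biological candidate, was tested on 23 other Nodal and Smad targets. Their list and the bound were set before the test. By then the results above were known, including values of its members Eomes and Wnt3. The median of the 23, log2 0.09, lay at percentile 89.64 of random lists, short of the bound, so the prediction was not met. Of the 23, 13 lay above 0 and 1 was at least 2-fold higher. With 1 array per condition this test gives a higher Nodal signal no support and does not exclude it. The Nodal explanation and other effects of the Ctcfl line may each apply and stay open.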

How the results depend on the processing

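The split that sets wild-type undifferentiated and Ctcfl-line retinoic acid cells against the remaining cells was chosen after seeing the data. It gave 0 limma calls, with 336 of 18310 genes at an unadjusted p under 0.05, fewer than unchanged genes alone would give. Its error holds the line effect, which favours a count of 0, so it is no check on the line calls. With a 3-fold threshold the counts of genes apart were, by construction, 338 and 285 for retinoic acid in wild-type and Ctcfl-line cells, 49 and 48 for the line in undifferentiated and retinoic acid cells, and 96 for the difference of responses. A 2-fold limit left 672 of the 1217 retinoic acid calls. The 8 line calls became 23 with quantile normalization and 15 with the variance prior that follows mean expression, all 8 shared each time; the cause was not tested. Pearson's r of the retinoic acid differences was 0.644 without the filter and 0.706 with a filter at log2 7, and that of the line differences 0.229 without the filter, as low signals came in or went out. Of the 40 list medians that stood apart, 0 changed sign. Without the filter the line difference in retinoic acid no longer stood apart for glycolysis (log2 -0.13) and histones (-0.16); with a filter at log2 7, mesenchyme with retinoic acid in the Ctcfl line (0.20) and the protocadherin response (0.32); with quantile normalization, the same pair (0.12 and 0.12) and glycolysis (-0.10); with the mean of probe sets, imprinted genes (-0.11) and glycolysis (-0.12); with list means, unfolded protein genes (0.15) and histones (-0.16). Chromosome medians near 0 changed sign. Without the filter that of chromosome 1 in retinoic acid was log2 -0.0038 and that of chromosome 2 in undifferentiated cells -0.0051. With quantile normalization chromosomes 1, 2 and 9 in retinoic acid had -0.0232, -0.0256 and -0.0014 and chromosome 2 in undifferentiated cells -0.0078. Each stayed above the range of random gene sets, at percentiles of at least 99.81. The median line difference of all genes in retinoic acid also moved down with quantile normalization, from log2 -0.0227 to -0.0496. Signals near the background of olfactory receptor genes, with medians between log2 4.68 and 4.78, compress differences, so low genes limit what can be seen.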

Other observations

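The microRNA genes described here were chosen after their values were seen, and no explanation of them was tested. The microRNA cluster Mir302, expressed in pluripotent cells, fell with retinoic acid in limma: Mir302a (adjusted p = 2.61e-05), Mir302c (adjusted p = 2.61e-05), Mir367 (adjusted p = 3.97e-05), Mir302d (adjusted p = 7.92e-05) and Mir302b (adjusted p = 0.000722). Their signals with retinoic acid were near or below the medians of olfactory receptor genes, which lay between log2 4.68 and 4.78, so no folds are given. Mir290a, from another cluster of pluripotent cells, fell (adjusted p = 0.0013), to signals of log2 5.53 and 5.16. Each was lower in 2 of 2 lines, which a limma call here all but requires, as its error is the difference between the lines. The transcript 4933403O08Rik, next to Tex16, was higher in the Ctcfl line by log2 2.32 in undifferentiated cells and 1.67 in retinoic acid (adjusted p = 0.0507 in limma).

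Several lists lay within the range of random lists in every comparison. With retinoic acid, in wild-type and Ctcfl-line cells, the medians were log2 0.13 and 0.02 for the cell cycle, -0.06 and 0.04 for p53 targets, -0.21 and 0.04 for the interferon response, 0.20 and 0.15 for mitochondrially encoded genes, -0.09 and -0.08 for oxidative phosphorylation, 0.09 and 0.15 for neural crest, 0.01 and -0.18 for blood and endothelium, 0.35 and 0.28 for Y-linked genes, and 0.04 and -0.10 for DNA methylation and polycomb. In limma 2 of 48 cell cycle genes rose with retinoic acid (1 adjusted over the list alone). Of 25 p53 targets 1 rose and 2 fell (1 and 3 adjusted over the list alone), and of 20 interferon genes 1 rose and 1 fell, as also adjusted over the list alone. Of 13 neural crest genes 2 rose and 1 fell, also adjusted over the list alone; the endothelin receptor gene Ednrb rose 12.4-fold (adjusted p = 0.000335). Of 14 blood and endothelium genes 1 rose, also adjusted over the list alone. Of 23 genes of DNA methylation and polycomb 1 rose and 3 fell (3 and 6 adjusted over the list alone). Of 70 oxidative phosphorylation, 10 mitochondrially encoded and 3 Y-linked genes 0 changed, also adjusted over the list alone. The glia list, by contrast, stood apart in the difference of responses and in no other comparison. Of its 18 genes 2 rose and 1 fell with retinoic acid (3 and 2 adjusted over the list alone).

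Of 20 chromosomes, the median line difference lay below the range of random gene sets in both states for 4 (chromosomes 6, 7, 11 and 13) and above it in both for 6 (chromosomes 1, 2, 8, 17, 19 and X), by the same percentiles as for lists. In undifferentiated and retinoic acid cells the medians were log2 -0.10 and -0.12 for chromosome 6, -0.07 and -0.09 for chromosome 7, -0.06 and -0.05 for chromosome 11, and -0.05 and -0.08 for chromosome 13. They were log2 0.06 and 0.05 for chromosome X, 0.04 and 0.08 for chromosome 19, 0.02 and 0.07 for chromosome 8, and 0.01 and 0.04 for chromosome 17. For chromosomes 1 and 2 they were below log2 0.02 and changed sign under another setting, except that of chromosome 1 in undifferentiated cells. The medians that changed sign stayed above the range of random gene sets. With quantile normalization the median of chromosome 13 in undifferentiated cells, log2 -0.06, no longer lay outside the range. Random genes are independent and neighbouring genes need not be, so this is a description.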
